A study of Homo sapiens with 6 samples.

How the data were processed

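RNA of Y79 cells with a control hairpin (3 libraries) or a MYCN hairpin (3 libraries) was prepared by TRIzol extraction and poly(A) selection and sequenced from both fragment ends, per the labels. The deposited table holds estimated counts per gene symbol, 1 column per library, which the authors did not scale between libraries. About 12.5% to 12.8% of the values are not whole numbers. The genome build was GRCh38, per the submitters' processing notes. The aligner, counting program, strand setting and annotation are not given in the sources used here, nor are the hairpin sequences or the number of hairpins. Of 17035 rows, 22 held no values and were left out, which left 17013 genes, 476 of them at 0 in every library. The table holds 0 mitochondrially encoded genes of the list fixed for them.

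Groups and replicate numbers came from the library titles. No 2 replicates held identical values, and the chi-square per degree of freedom between replicate pairs was 1.73 to 4.23 over genes with at least 50 counts, so each library was counted as a sample. Depth was 15490263 to 16078416 counts per library. Intervals given for counts are exact 95% intervals and cover counting error only. CPM values are scaled by TMM factors.

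Estimated counts were rounded to whole numbers. Genes passing filterByExpr with its default minimum of 10 counts were tested (12819 genes with 99.95% of counts) with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersions and TMM scaling, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The standard error of a log2 fold change was derived from the F statistic. Before the data were examined, 42 gene lists were fixed from textbook knowledge, and 40 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists. The list of noncoding RNAs had 3 members in the table and was not tested. Member counts adjusted over the list alone differed from those over all genes by at most 1. The median, mean and test of a list differed in sign for inner retinal neuron, hypoxia, fatty acid, polycomb and MYC network genes, of which none was called.

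The rule for named genes was fixed beforehand. It takes MYCN, MYC, MYCL and MAX, then the 10 highest and 10 lowest log2 fold changes among called genes with at least 5 CPM in the higher group, separated libraries and an approved symbol, then for a described list the 2 members with the smallest p in each direction. Some genes this rule takes are not reported here. DDX1, NBAS, ATP5F1A, MTRNR2L8 and MTRNR2L2 were chosen after their values were seen.

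Positions and transcripts came from GENCODE 29, which uses GRCh38, with newer symbols matched through RefSeq synonyms. For each gene, 1 protein-coding transcript was used. A search scored 16330 7-base sequences in the 3' untranslated regions (UTRs, at least 50 bases) of 12264 genes: log2 fold changes were regressed on transcript and UTR length, GC content and abundance, ranked, and averaged over the genes with the sequence, with 100 shuffles of the genes as reference. The sites described are the 2 leading 6-base sequences that share no 5-base stretch, each with its lowest-scoring 1-base extension at the 5' end. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

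The methods were tested on simulated data. For the comparison of MYCN and control hairpins with 12730 genes and 200 changed, 56.7% of genes changed 1.2-fold, 92.5% of those changed 1.5-fold and 97.0% of those changed 2-fold were recovered, and 16 unchanged genes were called. The changes were balanced between directions and few, whereas 75.8% of genes were called in the real data. The simulation therefore does not test the scaling where most genes differ. Camera called 0 of 40 lists in data without change and found a list lowered by 0.4. Genes were drawn independently in these data, whereas the correlation estimated for real ribosomal protein genes was 0.292. False calls of lists whose members move together were therefore not tested. In shuffled fold changes the sequence search ranked 10 of 10 planted 7-base sequences lowest. The planted log2 drop was 0.3, larger than the adjusted medians of -0.16 and -0.13 of the 2 sites described. Recovery of drops of that smaller size was not tested.

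Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper quartile and library size scaling, no filter or a filter of 1 CPM in 3 libraries, a 2-fold minimum, a replicate block, each library left out, an estimated correlation, and fry. Removal of genes with a 7-base site and of length and GC trends was added after the data were seen. Both of these settings also left out tested genes without a transcript model.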

Results

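Poly(A)-selected RNA was sequenced from Y79, an established human retinoblastoma line that grows in suspension and carries an amplified MYCN gene. The cells carried either a control hairpin or a hairpin against MYCN, a transcription factor of the MYC family that drives growth and proliferation, and the comparison asks which transcripts differ when MYCN is targeted. Each group held 3 libraries, which the series text describes as independent biological replicates, and the labels place all 6 in 1 batch. The deposited estimated counts summed to 16078416, 15975017 and 15515994 in control replicates 1, 2 and 3, and to 15762707, 15509106 and 15490263 in MYCN hairpin replicates 1, 2 and 3. Replicates were close, with a biological coefficient of variation of 3.34%. The p-values of single genes measure spread between these libraries. The number of hairpins is not known here, so spread between hairpins was not measured.

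MYCN (chromosome 2, 15940564 to 15947007, GRCh38) was lower with its hairpin in all 3 libraries, although the transcript stayed abundant. It stood at 3016.5 ± 129 CPM (SD, n = 3) with the control hairpin and at 2297.5 ± 110 (SD, n = 3) with the MYCN hairpin. In single libraries it measured 3045.8, 3127.9 and 2875.8 CPM in the controls and 2413.4, 2283.8 and 2195.2 CPM with the MYCN hairpin. MYCN fell by 0.39 ± 0.043 on the log2 scale (SE; edgeR quasi-likelihood test, adjusted p = 8.0e-11). The 40 genes nearest to MYCN in abundance had a median log2 fold change of -0.53, so this decrease was no larger than that of other abundant transcripts. DDX1, an RNA helicase gene upstream of MYCN (chromosome 2, 15591178 to 15631111), fell by 0.39 ± 0.042, from 6298.7 ± 104 to 4803.2 ± 47.8 CPM, while NBAS, the next tested gene beyond it, had a log2 fold change of -0.04 (adjusted p = 0.315). With library sizes as the only scaling, the log2 fold change of MYCN was -0.21.

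MYC (chromosome 8, 127735434 to 127741434), the paralogue of MYCN, rose from 0.380 ± 0.029 to 3.07 ± 0.75 CPM, a log2 fold change of 2.99 ± 0.299 (adjusted p = 6.2e-12). It stayed far below MYCN: the control libraries held 17 MYC counts together and the MYCN hairpin libraries 153, a ratio of 8.07 with a 95% exact counting interval of 4.88 to 14.2. MAX (chromosome 14, 65006174 to 65102695), the partner with which MYC proteins bind DNA, fell by 0.65 ± 0.056 from 65.3 ± 4.8 to 41.5 ± 1.1 CPM (adjusted p = 7.2e-14). MYCL measured 6.87 ± 0.55 and 6.52 ± 1.2 CPM, which did not pass the test (log2 fold change -0.07 ± 0.133, adjusted p = 0.619).

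**Figure D1:**
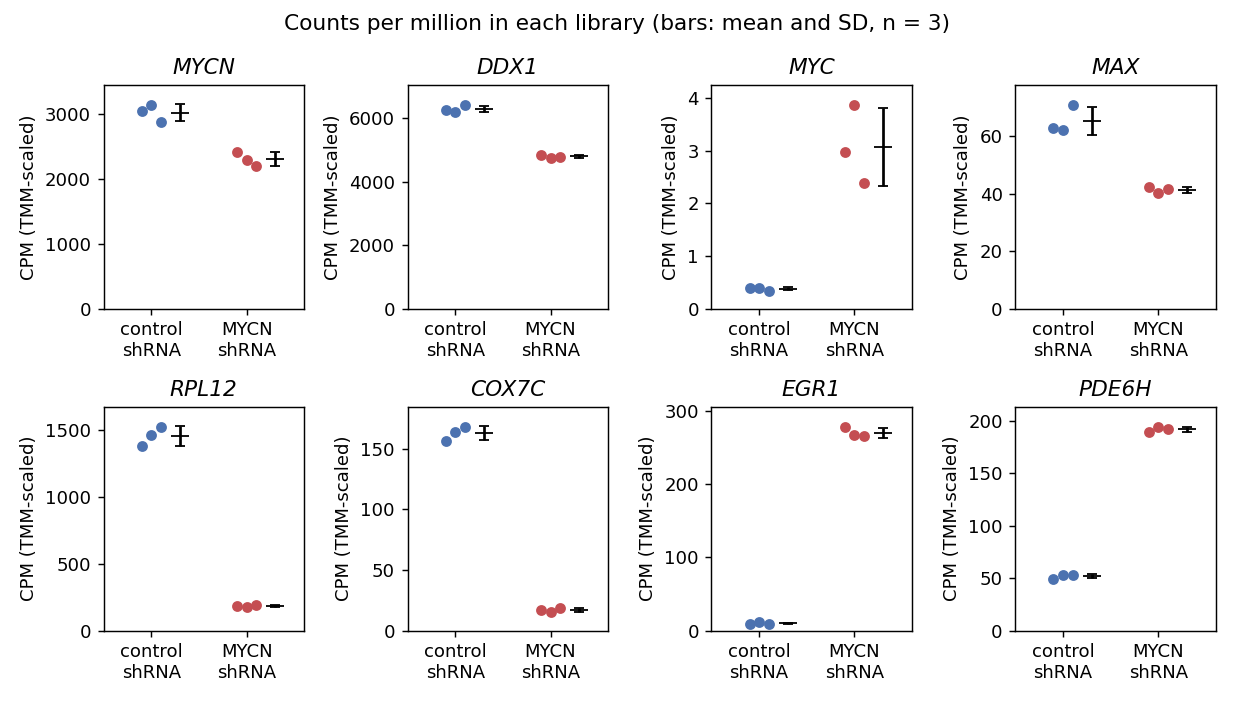
TMM-scaled CPM of 8 genes in each of the 6 libraries, with control hairpin libraries in blue, MYCN hairpin libraries in red, and the mean and SD (n = 3) in black beside them; each axis starts at 0. The 3 MYCN hairpin libraries lie below all controls for MYCN, DDX1, MAX, RPL12 and COX7C and above all controls for MYC, EGR1 and PDE6H.

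Most of the transcriptome differed between the groups. Of 12819 genes tested, 4865 were higher and 4857 lower with the MYCN hairpin (edgeR quasi-likelihood test, adjusted p under 0.05), and 1184 and 673 of these differed by at least 2-fold. The libraries of both groups did not overlap for 76.8% of tested genes, where chance gives 10%. This split between directions rests on the TMM scaling, whose factors were 0.930 to 0.948 in controls and 1.059 to 1.070 with the MYCN hairpin. With library sizes alone the median log2 fold change of all genes moved from 0.01 to 0.19, and 6597 genes were higher and 3348 lower. The 10 most abundant genes held 9.34% to 9.74% of counts in controls and 6.52% to 6.70% with the MYCN hairpin. They include the humanin-like genes MTRNR2L8 and MTRNR2L2, which resemble the mitochondrial 16S ribosomal RNA gene, and their counts are uncertain for that reason. Humanin-like genes together held 2.20% to 2.57% of counts in controls and 1.55% to 1.74% with the MYCN hairpin. Fold changes followed abundance: the median was 0.26 among the 1750 genes up to 2 on the log2 CPM scale and -0.66 among the 67 genes above 10. ATP5F1A, which encodes a subunit of ATP synthase and was the most abundant transcript, fell by 0.73 from 30249 ± 1077 to 18186 ± 471 CPM.

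**Figure D2:**
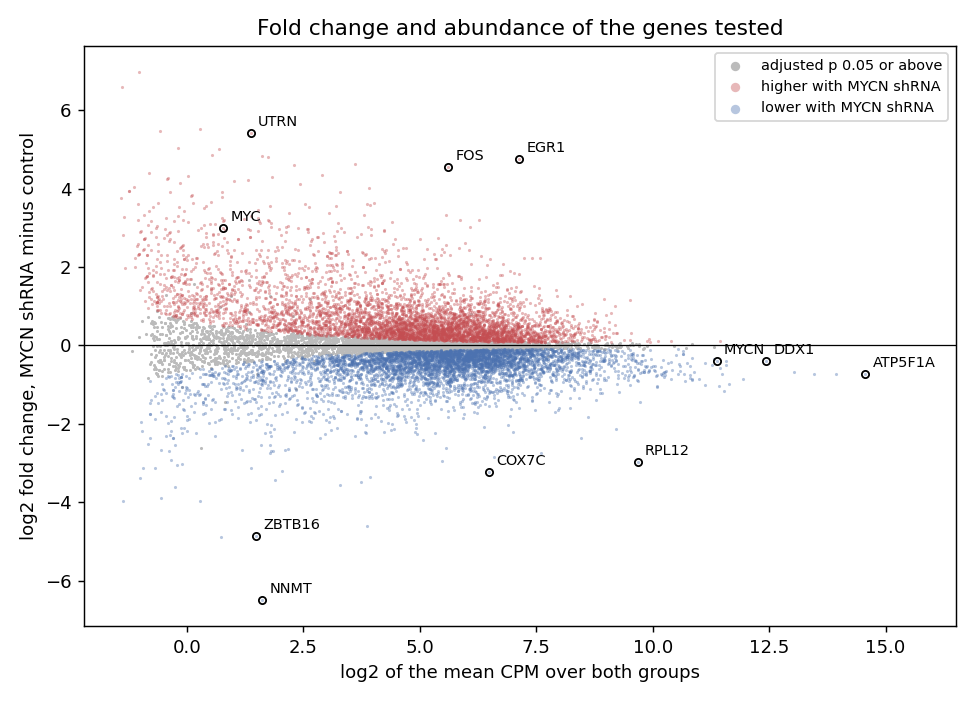
Log2 fold change of each of the 12819 genes tested (MYCN hairpin minus control, vertical axis) against the log2 of its mean CPM (horizontal axis), with 4865 genes called higher in red, 4857 called lower in blue and the rest in grey. Circled genes are named in the text, and the abundant genes at the right lie mostly below 0.

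Among the genes with the highest log2 fold changes were immediate early transcription factors and an extracellular matrix gene. EGR1 rose by 4.75 ± 0.059, from 10.002 ± 1.0 to 270.4 ± 6.9 CPM (adjusted p = 8.0e-43), and FOS by 4.56 ± 0.172, from 3.95 ± 1.4 to 93.4 ± 9.2 CPM. FN1, which encodes fibronectin, rose by 4.61. UTRN (5.41), INPP4B (4.80), HAP1 (4.63), MCF2L2 (4.29), ABCA12 (4.11) and NAV2 (4.005) were also among the 10 highest. Several were near the detection limit in controls, where UTRN had 5 counts over the 3 libraries and INPP4B 10, and the ratio for UTRN was 45.4 with a 95% counting interval of 19.2 to 141. The log2 fold change of UTRN was 6.07 without control replicate 1.

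The lowest log2 fold changes included abundant housekeeping transcripts. RPL12, a protein of the large ribosomal subunit (chromosome 9, 127447674 to 127451405), fell by 2.98 ± 0.045 from 1456 ± 73.0 to 185 ± 6.9 CPM (adjusted p = 9.6e-40). COX7C, a subunit of cytochrome c oxidase (chromosome 5, 86617904 to 86620962), fell by 3.24 ± 0.058 from 163 ± 5.6 to 17.3 ± 1.6 CPM. NNMT, which encodes nicotinamide N-methyltransferase, and its neighbour ZBTB16, a zinc finger transcription factor gene, lie side by side on chromosome 11 (114059593 to 114313285) and both fell. NNMT had 273 counts in controls and 3 with the MYCN hairpin, a 101-fold ratio with a 95% counting interval of 34.4 to 495, and ZBTB16 had 243 and 9. The log2 fold change of NNMT was -6.49, and -7.33 without MYCN hairpin replicate 3. PAPPA2 (-4.61), the homeobox genes PKNOX2 (-3.44) and UNCX (-3.36), and the potassium channel gene KCNJ8 (-3.20) were also among the 10 lowest. UTP14C (-3.55) and TUBB2B (-3.48) completed them, and their counts are uncertain because UTP14A and TUBB2A are near-identical copies. UTP14C measured 1.61, 2.96 and 0 CPM in MYCN hairpin replicates 1, 2 and 3, and its log2 fold change was -4.45 without MYCN hairpin replicate 2 and -5.07 by limma-voom, while the replicate block ended its call (adjusted p = 0.0584). AGCACAA or GTGGATC, 7-base sequences that also occur in MYCN, lie in the transcript (GENCODE 29) of 7 of the 10 lowest genes and 4 of the 10 highest, and in the 3' untranslated region of 3 and 0. NNMT, ZBTB16 and UNCX carry neither. Either sequence occurs in 4888 of the 12574 tested genes with a transcript model, and in 46.6% of the 665 that were at least 2-fold lower against 38.4% of the others. Both sequences were chosen from these fold changes, so a p for this difference would restate that choice and none is given.

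Genes of ribosomes and of ribosome assembly were lower as groups. All 78 cytosolic ribosomal protein genes fell, with a median log2 fold change of -0.68 and a range from -2.98 to -0.37 (camera, adjusted p = 3.6e-26; adjusted p = 0.211 with an estimated correlation). RPL12 and RPL29 (967 ± 38.8 to 219 ± 8.0 CPM) led this list, and both carry AGCACAA, RPL29 within its coding region and RPL12 across the end of it. Of 50 MYC-responsive nucleolar and ribosome biogenesis genes, 47 fell and 3 rose, with a median of -0.76 (adjusted p = 1.2e-14; adjusted p = 0.211 with an estimated correlation). RRP9, a component of the U3 small nucleolar particle, fell by 1.47 and the helicase gene DDX21 by 1.12. POLR1E (0.32) and UBTF (0.21), which act in RNA polymerase I transcription, rose. Ribosomal protein genes have many processed pseudogenes, so single values depend on how shared reads were counted.

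Lists of other translation genes and of mitochondrial genes were also lower. Of 20 aminoacyl-tRNA synthetase genes 19 fell, among them MARS1 (-1.17) and LARS1 (-1.13), while HARS1 rose by 0.79 (median -0.64; adjusted p = 9.1e-08; adjusted p = 0.211 with an estimated correlation). Among 32 translation factors 26 fell and 2 rose, with EIF3I at -1.38 and EIF2S3 at -1.02 against EIF2S1 at 0.49 and EIF2B1 at 0.21 (adjusted p = 8.3e-07; adjusted p = 0.268 with an estimated correlation). Mitochondrial ribosome and import genes fell in 35 of 37 cases, including PHB2 (-1.64) and the mitochondrial transcription factor gene TFAM (-1.46) (adjusted p = 6.1e-09; adjusted p = 0.114 with an estimated correlation). Nuclear-encoded respiratory chain genes fell in 48 of 62 cases and rose in 2, with COX7C and NDUFA6 (-1.81) lowest (adjusted p = 8.8e-08; adjusted p = 0.263 with an estimated correlation). The 2 that rose, NDUFA8 (0.16) and NDUFB9 (0.10), lay close to the threshold, with adjusted p-values of up to 0.104 and 0.229 when a library was left out. Of the genes named here as lower, PHB2, TFAM, COX7C and EIF3I carry GTGGATC and NDUFA6 carries AGCACAA in the 3' UTR. MARS1 carries AGCACAA outside its 3' UTR, and LARS1 and EIF2S3 carry neither 7-base sequence. Members with neither had medians of -0.433 (mitochondrial ribosome and import), -0.324 (respiratory chain), -0.388 (translation factors) and -0.639 (synthetases).

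The lists for integrated stress, heat shock, amino acid transport, one-carbon metabolism and nucleotide synthesis were lower. In the ATF4 and integrated stress response list 23 of 29 genes fell and 4 rose (median -0.62; adjusted p = 1.9e-05; adjusted p = 0.238 with an estimated correlation). The asparagine synthetase gene ASNS fell from 271 ± 9.9 to 86.7 ± 4.4 CPM and VEGFA, which encodes an angiogenic growth factor, from 95.7 ± 2.6 to 26.6 ± 1.9 CPM, while ATF5 (1.56) and VLDLR (0.79) rose. Heat shock genes fell in 14 of 18 cases, among them HSPH1 (-1.23) and STIP1 (-0.98), while DNAJB4 (0.47) and DNAJB1 (0.32) rose (adjusted p = 6.4e-04; adjusted p = 0.268 with an estimated correlation). Their median was -0.395, and -0.201 among the 12 members with neither 7-base sequence. HSPH1 carries AGCACAA in its 3' UTR, and STIP1 carries neither. Glutamine and amino acid transport genes fell in 14 of 18 cases, with GOT2 at -1.60, whereas the transporter genes SLC1A4 (0.94) and SLC38A2 (0.31) rose (adjusted p = 0.00143; adjusted p = 0.238 with an estimated correlation). Their median was -0.511, with -1.056 in the 8 members that carry a 7-base sequence and -0.224 in the 10 that do not. Without genes that carry one the list was no longer called (adjusted p = 0.0866). Both sequences were chosen from these fold changes, so this split is no independent test, and some lists split the other way, as given below. GOT2 carries GTGGATC in its 3' UTR, and SLC1A4, which rose, carries AGCACAA outside its own. Serine, glycine and one-carbon genes fell in 12 of 17 cases, including GLDC (-1.23) and SHMT2 (-1.08), while TYMS (0.59) and SHMT1 (0.34) rose (adjusted p = 0.00765; adjusted p = 0.268 with an estimated correlation). Nucleotide synthesis genes fell in 17 of 25 cases and rose in 7, with IMPDH2 at -1.22 and NME1 at -0.90 against GMPS at 1.01 and RRM2 at 0.77 (adjusted p = 0.0163; adjusted p = 0.391 with an estimated correlation). Without genes that carry a 7-base sequence the nucleotide list was no longer called (adjusted p = 0.0574), with a median of -0.309 over 15 members against -0.403 over 25.

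Photoreceptor genes shared by cones or by all photoreceptors were higher, with 24 of 29 risen and 5 fallen (median 1.28; adjusted p = 4.2e-05; adjusted p = 0.248 with an estimated correlation). PDE6H, the inhibitory subunit of the cone phosphodiesterase, rose from 51.8 ± 2.1 to 192 ± 2.4 CPM, and THRB, a nuclear receptor gene of cone development, from 11.1 ± 0.75 to 60.6 ± 2.1 CPM. TULP1 (-0.86) and the transcription factor gene NEUROD1 (-0.74) fell. Rod genes did not pass as a list, with 8 risen and 4 fallen of 16 (adjusted p = 0.372): the rod transcription factor gene NRL rose from 145 ± 9.8 to 348 ± 6.8 CPM and RP1 from 2.52 ± 0.34 to 10.98 ± 1.5 CPM, while the rod phosphodiesterase gene PDE6A fell by 1.27 and GNB1 by 0.88. PDE6A carries both 7-base sequences and GNB1 carries AGCACAA in the 3' UTR, while NRL, RP1, PDE6H, THRB, TULP1 and NEUROD1 carry neither. Rod genes had a median of 0.596 over the 11 members with neither and -0.575 over the 5 that carry one. For the cone and shared list these medians were 1.663 over 18 and 0.652 over 11. Both sequences were chosen from these fold changes, so these splits are no independent test. No test compared the cone and rod lists with each other.

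Immediate early genes rose in 19 of 27 cases and fell in 4 (median 0.97; adjusted p = 5.0e-04; adjusted p = 0.211 with an estimated correlation). JUN rose from 27.4 ± 2.3 to 133 ± 9.0 CPM, while ATF3 (-0.54) and DUSP4 (-0.50) fell. Type I interferon genes rose in 15 of 18 cases, including CMPK2 (2.57) and PARP9 (1.92) (adjusted p = 0.00745; adjusted p = 0.218 with an estimated correlation). RSAD2, which overlaps CMPK2 on chromosome 2, fell by 0.74, and reads in the overlap cannot be assigned without strand. NF-kB and inflammatory genes rose in 10 of 13 cases, among them CD83 (1.70) and SOD2 (0.43) (adjusted p = 0.00612; adjusted p = 0.211 with an estimated correlation).

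Regulators of cell death and p53 targets were higher. In the BCL2 and caspase list 17 of 26 genes rose and 4 fell, or 5 adjusted over the list alone (adjusted p = 0.00612; adjusted p = 0.211 with an estimated correlation). BCL2, which restrains apoptosis, rose by 1.77, while the inhibitor gene BIRC5 fell by 1.69 and CYCS, which encodes cytochrome c, by 0.51. The median was 0.403, and 0.614 among the 21 members with neither 7-base sequence. BIRC5 carries both sequences and CYCS carries AGCACAA in the 3' UTR, while BCL2 carries neither. Of 33 p53 targets 20 rose and 9 fell, or 10 adjusted over the list alone (adjusted p = 0.0186; adjusted p = 0.440 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 303 ± 10.8 to 694 ± 40.7 CPM and TP53INP1 by 1.52, whereas AEN (-0.93) and CCNG1 (-0.62) fell.

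The lists for cholesterol synthesis, the unfolded protein response, matrix genes and histones completed those called higher. Cholesterol synthesis genes rose in 17 of 25 cases, including IDI1 (1.05) and ACAT2 (0.99), while TM7SF2 (-0.89) and CYP51A1 (-0.24; adjusted p = 0.228 with library sizes alone) fell (adjusted p = 0.00548; adjusted p = 0.211 with an estimated correlation). Unfolded protein response genes rose in 14 of 21 cases, among them CRELD2 (1.36) and DNAJB9 (0.95), although the sensor gene ERN1 (-1.49) and HERPUD1 (-1.23) fell (adjusted p = 0.0132; adjusted p = 0.211 with an estimated correlation). Matrix and mesenchymal genes rose in 14 of 24 cases and fell in 5, with TIMP3 at 2.57 and COL5A1 at 1.02 against COL6A1 at -1.21 and COL4A2 at -0.42 (adjusted p = 0.0294; adjusted p = 0.235 with an estimated correlation). Replication-dependent histone genes rose in 9 of 11 cases, such as H2BC21 (2.19) and H1-2 (1.64), while H2AC20 fell (adjusted p = 0.0346; adjusted p = 0.248 with an estimated correlation). Most transcripts of this histone class lack a poly(A) tail and their genes are near-identical, so these counts are uncertain. Without genes that carry a 7-base sequence or lack a transcript model, the cholesterol, matrix and histone lists were no longer called (adjusted p = 0.0545, 0.230 and 0.0912). Their medians stayed close, at 0.245 over 19 members against 0.297 over 25, 0.683 over 13 against 0.738 over 24, and 1.583 over 9 against 1.550 over 11. Of the histone members left out only 1 carries a sequence, so that lost call cannot be assigned to site carriers alone. Members that carry a sequence had higher medians for cholesterol (0.570 over 6) and matrix (0.793 over 11) than members with neither, and the 1 histone member stood at 1.185. The matrix and histone lists were also lost with library sizes alone (adjusted p = 0.142 and 0.180), where their medians were 0.920 and 1.731 against a median of 0.19 for all genes, and the histone list ranged up to an adjusted p of 0.0547 among the other scalings and filters.

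**Figure D3:**
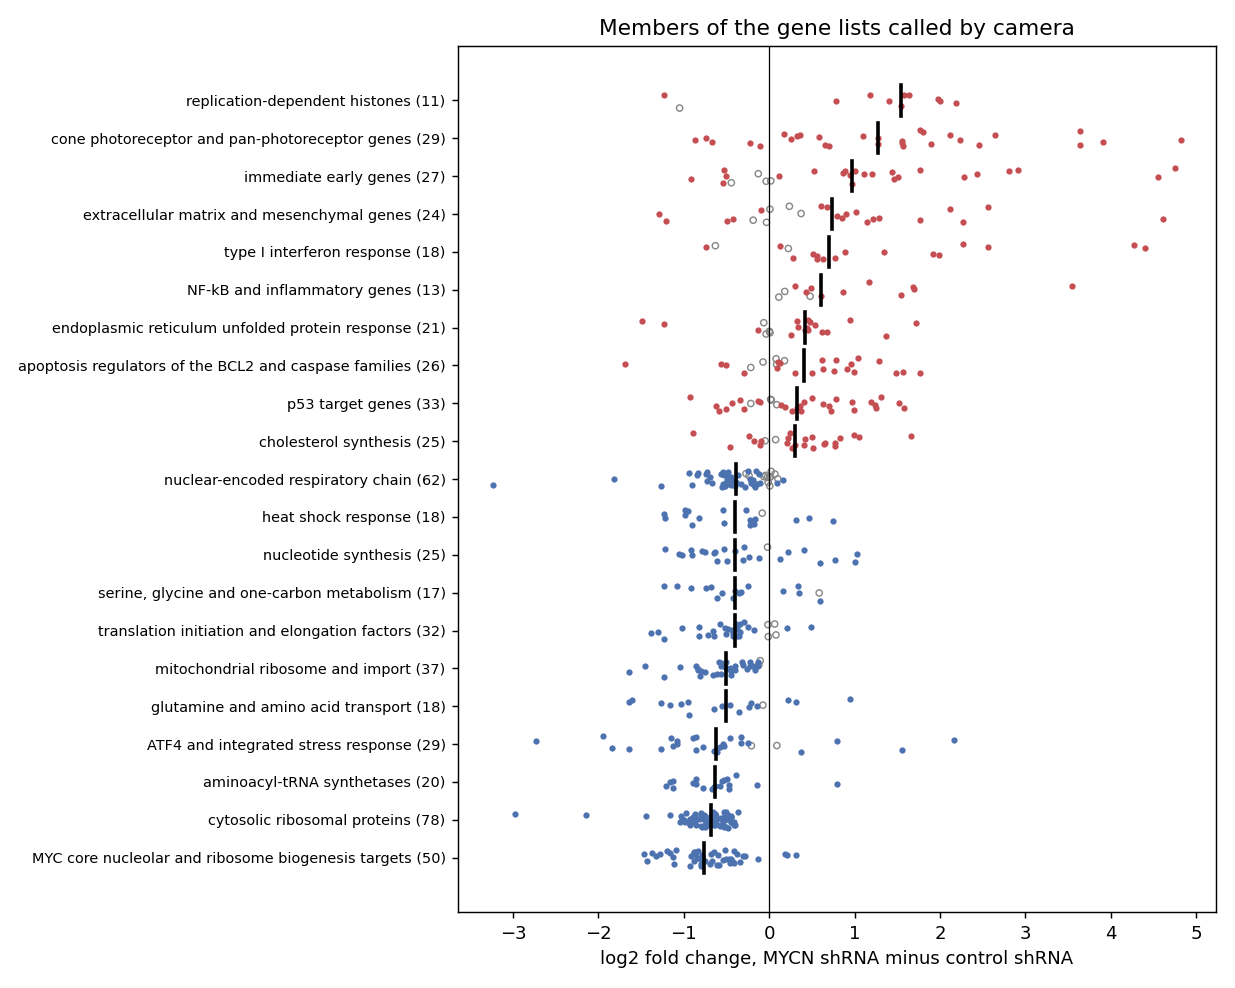
Log2 fold changes (MYCN hairpin minus control, horizontal axis) of the tested members of each called list, with the number of members in brackets. Filled points passed the gene test, blue in lists called lower and red in lists called higher, open grey points did not, and black bars mark medians, from -0.76 for nucleolar genes to 1.55 for histones.

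Cell cycle lists moved in both directions and were not called. Of 52 DNA replication and G1/S genes 21 rose and 23 fell (adjusted p = 0.717): CCNE2, a cyclin of S phase entry, rose from 59.5 ± 2.1 to 280 ± 5.3 CPM and CCNE1 by 1.39, whereas E2F2 (-1.09) and MCM10 (-0.93) fell. Among 50 G2/M genes 17 rose and 17 fell (adjusted p = 0.717), with PRC1 at 0.86 and GTSE1 at 0.59 against BIRC5 at -1.69 and MAD2L1 at -0.88. BIRC5 and MAD2L1 carry both 7-base sequences in the 3' UTR, GTSE1 carries neither, and PRC1 carries GTGGATC outside its 3' UTR. The MYC and MAX network was not called either, with 7 risen and 6 fallen of 17 (adjusted p = 0.979), including MLXIP (1.07), MXD1 (0.98), MXI1 (-0.996) and MLXIPL (-1.01). Polyamine genes rose in 3 and fell in 6 of 13 cases (adjusted p = 0.247): ODC1, the rate-limiting enzyme of polyamine synthesis and a known MYC target, fell from 651 ± 24.7 to 280 ± 11.8 CPM and DHPS by 0.86, while the catabolic gene SAT1 rose by 1.93 and ARG2 by 0.29. In glycolysis 9 genes rose and 13 fell of 24 (adjusted p = 0.111), with LDHA at -1.07 and PFKM at -1.22 against ENO2 at 0.75 and SLC2A1 at 0.62.

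Markers of other retinal and non-retinal cells were not called as lists. Retinal progenitor genes rose in 6 and fell in 8 of 18 cases (adjusted p = 0.717), with LIN28B (1.76) and LHX2 (1.02) higher and DLL3 (-2.24) and CCND1 (-2.26) lower. Müller glia genes rose in 6 and fell in 3 of 12 cases (adjusted p = 0.269), with VIM (0.68) and CLU (0.98) higher and SOX8 (-1.41) and GLUL (-0.35) lower. Inner retinal neuron genes rose in 5 and fell in 9 of 19 (adjusted p = 0.605), and pigment epithelium genes rose in 4 and fell in 2 of 10 (adjusted p = 0.495). Among the latter, MERTK rose from 9.57 ± 1.5 to 31.7 ± 1.1 CPM and RPE65, at a low level, from 0.244 ± 0.15 to 4.72 ± 0.21 CPM, while SERPINF1 fell from 450 ± 19.1 to 149 ± 3.6 CPM. OCA2 (-0.73, adjusted p = 0.042) lay close to the threshold, with adjusted p-values of 0.153 by DESeq2 and 0.232 without control replicate 1. Synapse and axon genes rose in 15 and fell in 19 of 37 (adjusted p = 0.362), with MAP2 (3.20) higher and STX1A (-1.81) and TUBB3 (-1.39) lower. Only 8 of 24 blood, immune and endothelial markers passed the count filter, of which 3 rose and 1 fell (adjusted p = 0.542), with VWF (2.95) and CLDN5 (1.01) higher and CD4 (-1.75) lower, each under 5 CPM in controls.

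The other lists that were not called had adjusted p-values of 0.151 for autophagy and lysosome, 0.716 for iron and glutathione, 0.717 for hypoxia, 0.717 for retinoblastoma oncogene candidates, 0.788 for fatty acid synthesis, 0.889 for polycomb and chromatin enzymes and 0.973 for antigen presentation. In total 10 lists were called higher and 11 lower of 40 tested. With a correlation estimated for each list 0 were called by camera, with 9 at an unadjusted p under 0.05 and a lowest adjusted p of 0.114, while fry, which asks only whether members move one way, called 17 higher and 18 lower.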

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

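The settings without genes that carry a 7-base site and with length and GC trends removed were added after the data were seen, and both also left out genes without a transcript model. MYCN carries both sites and was not tested without site genes, and its decrease is under the 2-fold minimum. In the other settings that tested it, MYCN stayed lower and past the threshold, between -0.43 and -0.21, and between -0.43 and -0.36 with each library left out. Of the 9722 called genes, 8959 were called in the same direction by DESeq2, 9651 by limma-voom, 8213 with library sizes alone, and 9168 to 9316 with a library left out, where 4681 to 4835 genes were higher and 4662 to 4852 lower. By construction fewer genes passed with a 2-fold minimum (1184 higher, 673 lower) and without genes that carry a site (3023 higher, 2761 lower). With an estimated correlation 0 lists were higher and 0 lower, and with fry 17 and 18. Each left-out library gave 10 lists higher and 11 lower. Without site genes the lists for nucleotide synthesis (adjusted p = 0.0574; median -0.309 against -0.403), amino acid transport (0.0866; -0.224 against -0.511), cholesterol (0.0545; 0.245 against 0.297), matrix (0.230; 0.683 against 0.738) and histones (0.0912; 1.583 against 1.550) were no longer called, over fewer members by construction.

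Whether the replicate numbers pair the samples stayed unclear. Deviations correlated weakly, at 0.120, 0.104 and 0.026 for equal numbers and at -0.142 to 0.040 for unequal ones. Each MYCN hairpin library correlated best with the control of its own number, but control 3 correlated best with MYCN hairpin 2 (0.040). With the replicate block 4967 genes were higher and 4939 lower, and UTP14C had an adjusted p of 0.0584, with a log2 fold change of -3.56 against -3.55.

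The direction turned for MYCL and for lists that were never called by camera, and the cause was not tested. MYCL was 0.107 with library sizes alone and -0.154 to 0.070 with a library left out, where it turned only without MYCN hairpin 3. Adjusted p-values of the turned lists were 0.773 for G2/M with library sizes alone. For the MYC and MAX network they were 0.99958 with upper quartile factors, 0.933 with library sizes alone, 0.966 without a filter, 0.996 with the replicate block, 0.912 with fry and 0.913 without site genes. With a library left out, this list ranged from 0.885 to 0.999 and turned without control 3 (0.898) and without MYCN hairpin 1 (0.951). For antigen presentation they were 0.821 without a filter, 0.996 with the replicate block, 0.912 with fry, 0.956 without site genes, 0.903 without length and GC trends and 0.822 to 0.964 with a library left out. For hypoxia, oncogene candidates and polycomb they were 0.956 without site genes, and for polycomb 0.729 without length and GC trends. Depth limits values of genes with few counts in a group, such as NNMT, UTRN and MYC.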

Other observations

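The tests of short sequences, list medians, gene dose, abundance, chromosomes, the miR-17-92 cluster and the sites of miR-17 and miR-124 were chosen after the results they address were seen, whereas the sites of the other 8 microRNA families were written down, and the count of sample splits planned, before. Genes with a 3' UTR site of miR-124 (GTGCCTT), a microRNA of neurons and retina, were higher after adjustment for length, GC content and abundance, with medians of 0.05 in 1879 genes with the site and -0.03 in the others. This site was singled out because it had the highest score of the 16330 sequences searched, 6.17 against at most 4.86 in 100 shuffles, so no separate p is given for it. Over 9 other microRNA families, sites of let-7, miR-9, miR-182, miR-183 and miR-96 had adjusted p-values of 0.188, 0.387, 0.903, 0.606 and 0.666 (permutation tests, two-sided).

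Around ATP5F1A on chromosome 18 (46080248 to 46104334), the adjacent gene HAUS1 was also abundant, at 1831 ± 53.5 CPM in controls and 1873 ± 19.7 CPM with the MYCN hairpin, at percentile 99.7 of tested genes in controls. HAUS1 did not pass the test (log2 fold change 0.03, edgeR adjusted p = 0.464), whereas ATP5F1A fell by 0.73.

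Genes whose 3' UTR carries AGCACAA (1397 genes) or GTGGATC (1154 genes) were lower with the MYCN hairpin, with adjusted medians of -0.16 and -0.13 against 0.001 and -0.008 in genes without, and scores of -9.54 and -7.83. Unadjusted medians were closer, at -0.079 against 0.015 for AGCACAA and -0.063 against 0.011 for GTGGATC. By sign, 55.8% against 48.7% and 54.5% against 49.0% of these genes were lower. Both scores, taken after length, GC content and abundance were regressed out, lie beyond 4.86, the most extreme among 16330 sequences in 100 shuffles. The weaker was still -6.88 in UTRs without exact matches to a set of short Alu sequences, a filter that left 438 of the 1154 genes with GTGGATC. This argues against chance, these trends and the Alu sequences matched as the whole cause. Diverged or partial Alu copies may remain after that filter. Both sequences occur in the coding region of MYCN, AGCACAA in exon 3 (chromosome 2, 15945688 to 15945694, within CCCATCCACCAGCAGCACAAC) and GTGGATC in exon 2 (15942623 to 15942629, within GGCCGCCGAGTGCGTGGATCC), but these were 2 of 8 lower sequences beyond the shuffles, 7 of which hold GCACAA or TGGATC, and the other 6, GCACAAA (-8.62) in rank 2 among them, do not occur in MYCN. AGCACAA and GTGGATC are the lowest-scoring extensions, at the 5' end, of the 2 leading 6-base sequences. Chance would put both 6-base sequences in MYCN in 16.6% of cases, so the presence of these 2 decides nothing. That figure does not cover the 7-base sequences, of which 13.6% of those scored occur in MYCN. The search was chosen after the results were seen, so no chance is given for both 7-base sequences. A candidate explanation, open because the hairpin sequences are not given, is seed-matched silencing by hairpins directed at MYCN. Genes with the site in coding sequence but not in the 3' UTR were lower too (adjusted medians -0.08 and -0.12; permutation p = 1e-05 for each, the smallest possible; adjusted p = 1.0e-05). This does not decide for silencing, because both sequences were chosen from these fold changes and no other coding sequences were scored beside them. Genes with the other site in the 3' UTR were also kept in.

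The decrease of ribosomal protein genes did not rest on these sequences, since the 62 members with neither site had a median log2 fold change of -0.667 (SE 0.037). Each SE of a median here was taken over member genes as if independent, although the correlation estimated for the list was 0.292. It does not measure spread between libraries. Removal of length and GC trends left the median at -0.686, and scaling by library size alone left it at -0.497, below 0 in each case by more than 2 SE. The biological explanation the design names, lower MYCN activity, may account for it, and stays a hypothesis because no test here separates it from other responses to the hairpin or from the lower fold changes of abundant genes in general.

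The decrease of MYCN mRNA was small. The choice of TMM over library sizes is not its whole cause, as MYCN stayed at -0.211 with library sizes alone (adjusted p = 2.4e-05). Both scalings are relative, so neither can show a change in the amount of RNA per cell. The decrease may belong to one shared by abundant transcripts, since MYCN lay at percentile 65.0 of the 40 genes nearest in abundance, and at 47.5 with ribosomal proteins and translation factors left out. A lower dose of the co-amplified region cannot be told apart from silencing, because DDX1 differed from MYCN by 0.002 (SE 0.060) but NBAS by 0.351 (SE 0.057), and the extent of the amplified region is not known here. MYCN protein was not analysed here.

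Whether cultures differed by a gained or lost chromosome was also tested: the chromosome median farthest from 0 was 0.173, on chromosome 18, within the 0.3 bound set for a whole copy. Lower activity of the miR-17-92 cluster, a known MYC target, could raise its targets, but 1 of 4 seed families passed: miR-18 had an adjusted p of 0.045, miR-19 0.115, miR-92 0.115 and miR-17 0.188, all with positive scores.

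The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Of these 1, the real split, called as many genes, 9722 against at most 0 in the others (edgeR; at most 30 at an unadjusted p under 0.05, and 0 by limma-voom). Likewise 1 of 10 splits called as many lists, 21 against 10 to 14 in the others, each of which still mixes libraries of both groups unevenly.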
